A study of Homo sapiens with 48 samples.

How the data were processed

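RNA of 48 THP-1 samples was measured on microarrays in 3 dyes. The values are deposited log2 values of 45220 features per sample, from 6.05 to 16.00, with sample medians between 7.68 and 7.70. R 2.3 and limma are named in the submitters' processing notes. The near identical distributions were found in the values; the method of normalisation and background correction is not given in the sources used here. Groups, times and dyes came from the sample labels. Columns were assigned to samples by name, and 0 columns belonged to no labelled sample. No 2 samples held identical values.

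Of the features, 35268 had 1 gene symbol, 0 had several and 9952 were unnamed here. Symbols were updated through the gene identifier for 35128 features in a RefSeq table, and 140 kept the symbol of the platform annotation. The feature with the highest mean over all samples stood for each of 20399 symbols, of which 5896 had more than 1 feature. Different features of one gene were not reconciled further.

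Tests used limma 3.58.1 in R 4.3.3 on the log2 values as deposited: one fit of all 48 samples with 14 groups and dye as a fixed term, moderated variances and Benjamini-Hochberg adjustment within each contrast at 0.05. The labelled array was planned as a random block, to be left out if its consensus correlation fell below 0. It was -0.0224, so the fit had no array block. The fit had 32 residual degrees of freedom. The 33 gene lists were fixed before the data were examined and tested with cameraPR at a preset inter-gene correlation of 0.01, adjusted over 396 tests. They were tested again with camera and an estimated correlation. A list member with no measured current symbol was looked up among the synonyms; members not found were not analysed here. Named genes, by a rule fixed before the data were examined, were those with adjusted p under 0.05 whose exposed samples all lay on the side of the fold change relative to controls of the same dye, the 10 largest and 10 smallest fold changes per contrast, plus list members past the threshold.

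The title numbers of the exposed samples follow the dye, and a letter in the sample code could pair samples. Deviations from the group means of samples with the same letter correlated with a mean of 0.0059 and a lowest pair of -0.84, and those of the same dye with 0.02 and -0.81. No pairing by these labels was seen. Pairing is not excluded, because these labels may be out of step with the columns, as described below.

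The surface of each array was examined from the order of the features, which number from 1 to 45220. Deviations of each feature from its median over samples were laid out in rows of 85, the first local maximum of their autocorrelation that divides the number of spots, giving 532 rows. The surface component was the median over 11 by 11 spots. This examination, and the row width, were chosen after the data had been seen. A first choice of 170 per row gave 45 rather than 46 samples whose best match lay 20 or 40 columns away. Samples were not reassigned to other groups.

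Other settings, chosen before the data were examined, were leaving out the dye term, a letter block, the array block, slide as a term, quantile normalisation, median centring, leaving out the dimmest genes, the mean of a gene's features, a trended robust variance, fits of the contrast's own groups, controls of a single code, and leaving out each sample. Removal of the surface component, a block of the columns sharing surface marks, and leaving out the 6 samples with a surface SD above 0.2 were added after seeing the data. The 6 samples included Fullerene 6 h replicate 1, tCNT 6 h replicate 3 and Baytube 6 h replicate 3. The others were tCNT 24 h replicate 1, Graphite 24 h replicate 1 and control 6 h replicate 5. The scripts were tested on simulated values with the residual SD of each of 20399 genes for the Graphite 6 h contrast, where 55.2% of genes changed 2-fold and 89.4% of genes changed 4-fold were recovered, and 4 unchanged genes were called.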

Results

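Gene expression was measured in 48 samples of THP-1 cells, an established human monocytic line turned into macrophage-like cells with the phorbol ester PMA. The labels name 6 carbon materials, written rCNT, tCNT, Baytube, Graphite, Fullerene and SES, each given at 100 µg for 6 or 24 h. Each of the 12 exposed groups had 3 samples, and each of the 2 medium control groups had 6. Nothing in the labels says that the samples of a group were separate cultures. The p-values rest on the spread between samples within groups, pooled over the 14 groups, which may be technical. The samples were hybridised in 3 dyes to 20 arrays on 5 slides. With 3 exposed and 6 control samples the precision was limited: the median SE of a log2 fold change between a material and its control was 0.26. The fit behind this SE took the samples as independent.

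Transcripts known from macrophages were measured in all samples. The transcript of MMP9, a secreted gelatinase, had a mean log2 value of 15.71 ± 0.39 (SD, n = 48), and CD68, a lysosomal glycoprotein, 13.74 ± 0.86 (SD, n = 48). HMOX1, the haem-degrading oxygenase, stood at 14.97 ± 0.52 (SD, n = 48), and the cytokine gene IL1B at 15.21 ± 1.04 (SD, n = 48). MMP9, HMOX1 and IL1B reached 15.98 to 16.00 in at least 1 sample, the end of the scale, so saturation was not ruled out for them. Of the promyelocyte genes, MPO had a mean of 6.61 ± 0.25, ELANE of 11.59 ± 1.00 and AZU1 of 13.44 ± 0.96 (SD, n = 48). Among markers of other cell types, the epithelial gene EPCAM had a mean of 6.73 ± 0.19 and KRT8 of 8.91 ± 0.44 (SD, n = 48). The fibroblast gene COL1A1 stood at 6.83 ± 0.13 and PDGFRA at 9.32 ± 0.75, and the lymphocyte genes CD79A at 10.64 ± 0.74 and GNLY at 11.3 ± 0.38 (SD, n = 48). Levels of different probes are not comparable, so these values do not rank the genes. The lymphocyte, epithelial and fibroblast lists were called in no material contrast.

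The columns of the deposited table did not match their labels in one measurable respect, and for this reason every group below is a group of samples so labelled. Samples of different dye on one array share its surface, so smooth marks such as stains and scratches were compared between samples. The surface component of 46 of the 48 samples matched best a sample 20 or 40 columns away in the table. These 36 pairs had a median surface correlation across spots of 0.85 (permutation test, one-sided, p = 1e-05, the smallest that 100000 permutations can give). The 38 pairs that the labels place on one array had a median of -0.08 (permutation test, one-sided, p = 0.719). Of the 46 samples with a labelled array partner, 0 had that partner as best match. No labelled pair was also 20 or 40 columns apart. Over all genes, samples of one labelled group correlated with a mean r of -0.0089 in their deviations from the gene means, and samples of different groups with -0.0090 (permutation test, one-sided, p = 0.472). Samples 20 or 40 columns apart correlated with a mean r of 0.63, and 0.57 with the surface component removed, against -0.03 for other columns. The most similar sample lay 20 or 40 columns away for 34 of 48 samples, was of the same labelled group for 1 and shared the labelled array for 0. Between the labelled dyes 533 genes differed (limma), and between the first 20, next 20 and last 8 columns 1578. These comparisons of columns were chosen after seeing the data.

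**Figure D1:**
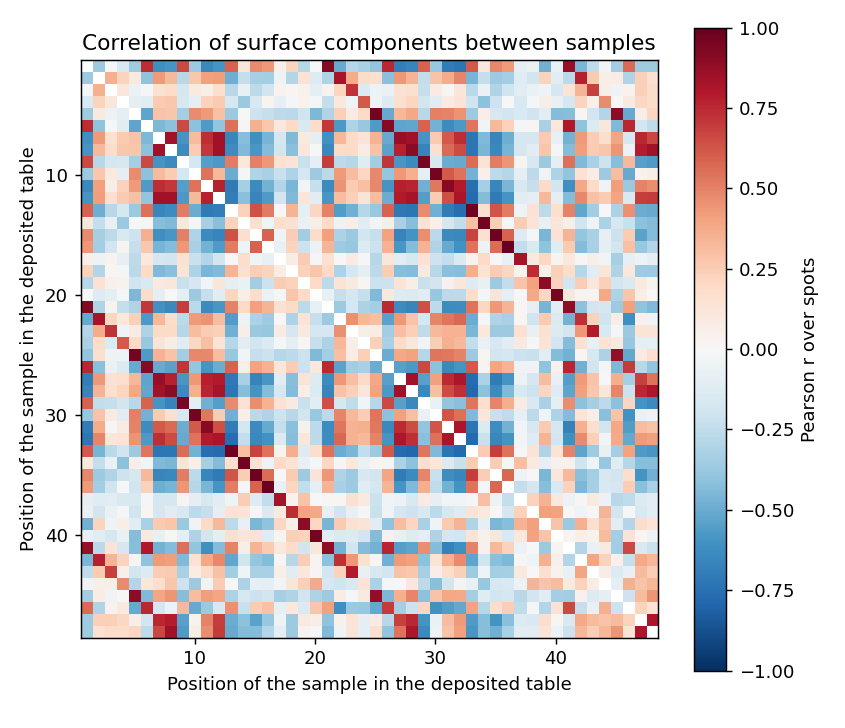
Pearson correlation across spots of the surface components of each pair of the 48 samples, in the order of the deposited table on both axes; colour gives r from -1 to 1 and the white diagonal is left empty. Dark red lines run parallel to the diagonal at distances of 20 and 40 columns, where the median r was 0.85.

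The comparison of each material with its time-matched control asks which genes responded to that material. In samples labelled Fullerene 6 h, 22 genes were higher and 69 lower than in the 6 h control (limma, adjusted p under 0.05), of which 7 and 66 changed at least 2-fold. PSME1, a proteasome activator subunit, was lower by a log2 fold change of -3.94 ± 0.77 (SE; limma adjusted p = 0.00992), with a mean of 9.70 ± 3.14 (SD, n = 3) against 13.63 ± 0.33 (SD, n = 6). The SEs pool the spread over all groups and do not measure that of the exposed samples alone. HARS1 and TM7SF3 had exposed SDs of 2.44 and 2.83, against 0.27 and 0.38 in controls. For PHF3 the SDs were closer, 0.57 and 0.33. HARS1, the histidyl-tRNA synthetase, was lower by -3.11 ± 0.62 (SE), EIF4A3, a core protein of the exon junction complex, by -2.87 ± 0.53 (SE), and BTG3, an antiproliferative factor, by -3.05 ± 0.57 (SE). PHF3 had the lowest adjusted p of the named genes, 0.00014 in limma, at a log2 fold change of -2.83 ± 0.38 (SE). HPS6, TM7SF3, QSER1, RPL13AP3 and PCYOX1L made up the rest of the 10 largest decreases that met the naming rule, between -3.56 and -2.56. These folds moved with single samples: PSME1 ran from -5.90, without Fullerene 6 h replicate 1, to -2.91, without replicate 2, TM7SF3 likewise from -5.29 to -2.58, and QSER1 from -4.18 to -2.03. The call of each of these 3 genes was lost without replicate 2. The heat shock chaperone gene HSPA1B fell by 1.66 on the log2 scale (SE 0.33, limma adjusted p = 0.011), and 3 of 14 measured heat shock chaperones passed when adjusted over the list alone, against 1 over all genes: HSPA1B, DNAJA1 at -0.76 ± 0.25 (SE) and BAG3 at 1.50 ± 0.48 (SE).

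Among the higher genes in samples labelled Fullerene 6 h that met the naming rule, NELFA, a subunit of the negative elongation factor, had the largest log2 fold change, 1.51 ± 0.37 (SE; limma adjusted p = 0.0499). The others included C1orf159 at 1.32 ± 0.31 (SE), PPM1M at 1.17 ± 0.28 (SE) and MBTPS1, a protease of the Golgi that activates SREBP factors, at 1.03 ± 0.25 (SE). YWHAB, XXYLT1 and NUDT3 lay between 0.83 and 0.91. MARK2P10, CLDN5 and LINC00517 were also called, but their control means of 6.87, 6.87 and 6.75 lay near the bottom of the scale, where signal over background was not examined, so no fold or rank is given. ACSBG1 also changed at least 2-fold and did not meet the rule; it was named after its values were seen. The called genes depended on single samples: 2 genes passed without Fullerene 6 h replicate 2, 8 without replicate 3 and 343 without replicate 1. Without replicate 1 the exposed samples left were replicates 2 and 3, which shared surface marks (r = 0.79) and are not independent. Against the controls of code 1 alone 14 genes passed, against those of code 6 alone 4, and in a fit of the contrast's own groups 0. With columns 20 or 40 apart as a block, chosen after seeing the data, the consensus correlation was 0.72 and 3 genes passed, 2 of them among the 91. The features of the 69 lower genes lay closer together on the array than random features, with a mean distance to the nearest of 7.95 spots against a median of 13.73 (permutation test, p = 1e-04, the smallest that 10000 draws can give).

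No gene passed in the other 11 material contrasts (limma). At an unadjusted p under 0.05, the counts at 6 h were 471 genes for rCNT, 1279 for tCNT, 192 for Baytube, 395 for Graphite and 138 for SES, against 2276 for Fullerene. At 24 h they were 917 for rCNT, 447 for tCNT, 957 for Baytube, 3202 for Graphite, 125 for Fullerene and 605 for SES, of 20399 genes. Without Baytube 24 h replicate 1, 189 genes passed for Baytube 24 h, and 16 without its replicate 2. For tCNT 6 h, 4, 19 and 23 genes passed without replicates 1, 2 and 3. In a fit of the contrast's own groups, 814 genes passed for Graphite 24 h. Graphite 24 h replicate 1 had the highest surface SD of all samples, 0.54, against a median of 0.11. With known folds added to 200 genes of the samples labelled Graphite 6 h, the test recovered 49.3% of those changed 2-fold, 89.4% of those changed 4-fold and 10.4% of those changed 1.5-fold. These shares assume that the labels name the right columns. If columns and labels are out of step, they do not tell how large an effect could be missed.

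Genes of cell division were called as a list in 4 contrasts, 1 lower and 3 higher, by a test with a preset correlation of 0.01 between genes. Members of this list correlated across samples with a mean r of 0.707, far above the preset, so a shift is not shown by these calls. In samples labelled SES 6 h all 22 measured proliferation genes had log2 fold changes below 0, with a mean of -0.93 (cameraPR adjusted p = 6.5e-10; adjusted p = 0.974 with an estimated correlation). TOP2A, the topoisomerase of mitotic chromosomes, stood at -1.27 ± 0.92 (SE) and TYMS, the thymidylate synthase, at -1.65 ± 1.01 (SE), and neither passed alone. The mean in SES 6 h ran from -1.39 to -0.58 on leaving out one sample. The same list had a mean of 0.56 in Baytube 6 h, with 22 members above 0 (cameraPR adjusted p = 0.00131; adjusted p = 0.974 with an estimated correlation). Leaving out one sample, that mean ran from -0.03, without Baytube 6 h replicate 3, to 1.23. The list had a mean of 0.61 in rCNT 24 h (adjusted p = 0.014) and 0.39 in Fullerene 24 h (adjusted p = 0.0302). With an estimated correlation, adjusted p was 0.974 in both. Leaving out one sample, the mean in rCNT 24 h ran from 0.03, without its replicate 1, to 1.01, and that in Fullerene 24 h from 0.21, without control 24 h replicate 1, to 0.48. No list member passed over all genes or when adjusted over the list alone in these contrasts.

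Inflammatory genes had opposite signs at the 2 times in the samples labelled tCNT. All 15 measured NF-kB feedback and target genes were above 0 in tCNT 6 h, with a mean of 1.01 (cameraPR adjusted p = 0.000301), and 14 were below 0 in tCNT 24 h, with a mean of -0.69 (adjusted p = 0.000187). With an estimated correlation, adjusted p was 0.974 at both times. Leaving out one sample, the mean ran from 0.64, without tCNT 6 h replicate 2, to 1.30 at 6 h, and from -1.03 to -0.22, without tCNT 24 h replicate 2, at 24 h. TNFAIP6, a hyaluronan-binding protein induced by TNF, stood at 1.91 ± 1.16 (SE) at 6 h and the cyclooxygenase gene PTGS2 at 1.67 ± 1.14 (SE). Immediate early genes had means of 0.46 at 6 h (adjusted p = 0.0202) and -0.44 at 24 h (adjusted p = 0.0187). Adjusted p was 0.974 for both with an estimated correlation. Their means were 0.21 without tCNT 6 h replicate 1 and -0.16 without tCNT 24 h replicate 2. FOSB in tCNT 6 h passed when adjusted over the list alone, but its mean of 7.18 over all samples lay near the bottom of the scale, where signal over background was not examined, so no fold is given. NF-kB genes were also lower as a list in Baytube 24 h, at a mean of -0.60 (adjusted p = 0.00705), and in Graphite 24 h, at -0.69 (adjusted p = 0.0309). For both, adjusted p was 0.974 with an estimated correlation. The mean in Baytube 24 h turned to 0.04 without its replicate 1, and that in Graphite 24 h was -0.43 without its replicate 1. In Baytube 24 h the chemokine list had a mean of -0.76 (adjusted p = 0.0309) and the immediate early list -0.40 (adjusted p = 0.0202). Adjusted p was 0.974 for both with an estimated correlation. Without Baytube 24 h replicate 1 these means were 0.08 and -0.11. Of the 18 chemokine probes 8 reached 15.97 to 15.99, where the scale ends at 16.00, so saturation was not ruled out and the size of the chemokine mean is uncertain. SOD2 and NFKBIA of the NF-kB list and IER3 of the immediate early list also reached 15.97 to 15.99, so the sizes of those means are uncertain too.

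Interferon-stimulated genes had a mean of 0.45 in Baytube 6 h, with 18 of 21 members above 0 (cameraPR adjusted p = 2.9e-06), and 0.26 in SES 6 h (adjusted p = 0.0322). For both, adjusted p was 0.974 with an estimated correlation. Leaving out one sample, the mean in Baytube 6 h ran from 0.28, without its replicate 2, to 0.75. The mean in SES 6 h was 0.09 without control 6 h replicate 4 and -0.06 against the controls of code 1 alone. IFIT1, an RNA-binding antiviral protein, stood at 0.61 ± 0.53 (SE) in Baytube 6 h. Cholesterol synthesis genes had a mean of 0.50 in Graphite 6 h, with 14 of 15 above 0 (adjusted p = 0.000301; adjusted p = 0.886 with an estimated correlation). That mean was 0.24 without control 6 h replicate 5, whose list mean of 10.29 lay apart from the nearest control at 11.45. The call was lost without Graphite 6 h replicate 2 and against the controls of code 1 alone. Sets of columns 20 or 40 apart held 78.3% of the variance of this list. HMGCS1, the synthase ahead of the rate-limiting step, stood there at 0.72 ± 0.37 (SE). Actin cytoskeleton and adhesion genes had a mean of 0.43 in Graphite 6 h (adjusted p = 0.0145; adjusted p = 0.974 with an estimated correlation), and 0.09 without its replicate 1. That sample had a list mean of 13.83, against 12.82 and 12.98 for the other replicates and 12.53 to 12.96 in the 6 h controls. It was not alone: all samples in columns 1 to 4, 21 to 24 and 41 to 44 had list means of 13.62 to 13.83. All other samples had 12.38 to 13.09. No control lay in those columns, so a difference of these columns cannot be told apart from an effect in this contrast. Sets of columns 20 or 40 apart held 96.3% of the variance of this list (permutation test, p = 1e-05, the smallest possible).

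Metallothionein and zinc transport genes had a mean of -0.49 in rCNT 6 h, with 11 of 11 below 0 (adjusted p = 0.0268), and -0.94 in Graphite 24 h (adjusted p = 0.0322). Adjusted p was 0.974 for both with an estimated correlation. On leaving out one sample these means ran from -0.68 to -0.37 and from -1.02 to -0.81. Sets of columns 20 or 40 apart held 67.6% of the variance of this list. Among others, the calls were lost without rCNT 6 h replicate 1 and without Graphite 24 h replicate 2. In Graphite 24 h MT1B, MT1E and MT1F passed when adjusted over the list alone, MT1E at -2.74 ± 0.89 (SE), and 0 passed over all genes. The remaining calls in Baytube 6 h were oxidative phosphorylation at 0.19 (adjusted p = 0.0309), a list of which sets of columns 20 or 40 apart held 62.6% of the variance, and ribosomal proteins at -0.10 (adjusted p = 0.0213). For both, adjusted p was 0.974 with an estimated correlation. Of the 21 ribosomal probes all but RPL22 reached 15.97 to 15.99, where the scale ends at 16.00, so saturation was not ruled out and no change is read from that list. Its mean turned to 0.03 without Baytube 6 h replicate 2, and the oxidative phosphorylation mean was 0.11 without replicate 3. The amino acid response had a mean of 0.46 in rCNT 24 h (adjusted p = 0.0309), and monocyte and promyelocyte markers 0.44 in tCNT 24 h (adjusted p = 0.0499). Adjusted p was 0.974 for both with an estimated correlation. These means were 0.14 without rCNT 24 h replicate 1 and 0.17 without tCNT 24 h replicate 2. In all, 22 of 396 tests were called, 12 higher and 10 lower, and 0 with an estimated correlation. Of the 22, 8 were lost with the labelled slide as a term, 4 with the block of columns 20 or 40 apart, and 7 against the controls of code 6 alone. Against those of code 1 alone 8 were lost and 1 turned its sign. Labelled slides may be out of step with the columns, so the slide term need not adjust for the real slide. The other 21 lists had no call, with a lowest adjusted p of 0.06.

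**Figure D2:**
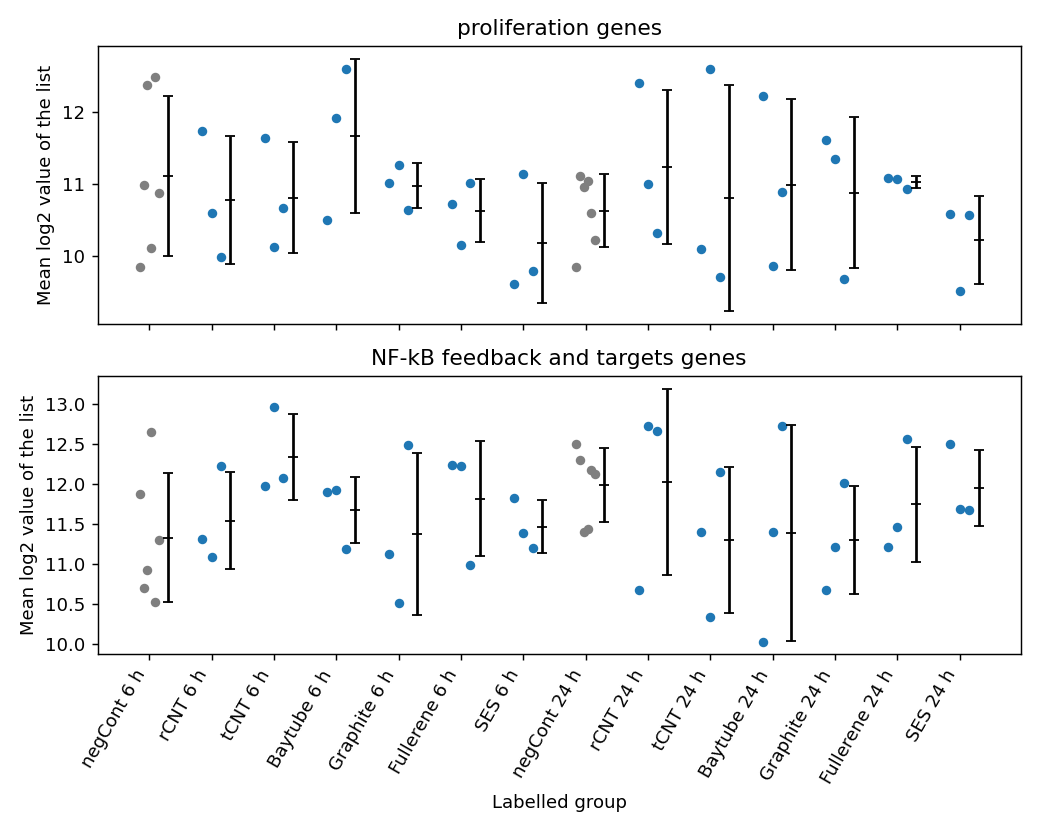
Mean log2 value of the proliferation list (top) and of the NF-kB list (bottom) in each sample, by labelled group; points are samples, grey for controls, and bars give the mean and SD of the group (n = 3, controls n = 6). Samples of one labelled group spread widely: the proliferation mean ran from 9.53 to 12.61 over all samples.

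For proliferation genes the labelled groups accounted for 18.1% of the variance of the list mean, against 27.6% expected by chance (permutation test, one-sided, p = 0.853), and for NF-kB genes for 19.8% against 27.7% (permutation test, one-sided, p = 0.798). The share was higher than expected for some lists: 37.1% for metallothioneins (permutation test, one-sided, p = 0.153), 39.2% for inflammasome components (permutation test, one-sided, p = 0.111) and 30.1% for cholesterol synthesis (permutation test, one-sided, p = 0.361). Over the 33 lists the lowest adjusted p was 0.998.

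Control samples at 24 h were compared with those at 6 h for the change with time alone. No gene passed (limma), and 232 had an unadjusted p under 0.05. The difference of each material's effect between the times gave 0 genes for all 6 materials, with unadjusted counts of 265 for rCNT, 606 for tCNT, 499 for Baytube, 1861 for Graphite, 878 for Fullerene and 328 for SES. The Fullerene difference rose to 105 genes without Fullerene 6 h replicate 1, which left replicates 2 and 3 with their shared surface marks. The 2 sets of controls, of codes 1 and 6, differed in 0 genes at both times, with 984 genes at an unadjusted p under 0.05 at 6 h and 142 at 24 h.

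The materials were also compared with each other, without the control. In the moderated F-test 27 genes differed among the 6 materials at 6 h and 0 at 24 h (limma), with 842 and 444 at an unadjusted p under 0.05. The count at 6 h was 2 without Fullerene 6 h replicate 2, 4 without replicate 3 and 140 without replicate 1; without tCNT 6 h replicates 1, 2 and 3 it was 60, 51 and 52. The direct contrast of rCNT with tCNT gave 0 genes at 6 h and at 24 h, with unadjusted counts of 770 and 143. Of the 15 pairs at 6 h, 5 gave calls: 36 genes for Graphite with Fullerene, 29 for Fullerene with SES, 18 for rCNT with Fullerene, 17 for Baytube with Fullerene and 1 for tCNT with Graphite. At 24 h all 15 pairs gave 0, with unadjusted counts from 143 to 2163. At 6 h rCNT with tCNT gave 13 without tCNT replicate 2 and 9 without replicate 3. Effects of 2 materials at 6 h correlated across genes with a mean r of 0.33 over 15 pairs, from -0.14 to 0.79. Genes are not independent replicates, and simulated unchanged groups against the same controls gave 0.33. The simulated values assume independent samples and leave out the correlation between columns 20 or 40 apart. The mean covariance was 0.0411, against 0.0484 simulated, and with the controls split by code the mean r was -0.06. At 24 h the mean r was 0.47, against 0.34 simulated with the same shared controls, and the mean covariance was 0.0718, against 0.0488 simulated. With the controls split by code the mean r at 24 h was 0.32, for which no simulated value was computed. Relabelling samples within a time gave as high a mean r in 47 of 100 draws at 6 h and 18 of 100 at 24 h. The highest pair at 6 h, tCNT with Fullerene, held tCNT replicate 3 and Fullerene replicate 1 (surface r = 0.97). The highest at 24 h, tCNT with Graphite at 0.815, held tCNT replicate 3 and Graphite replicate 2 (surface r = 0.73). At 6 h rCNT with Fullerene had an r of 0.65 and no samples 20 or 40 columns apart. Whether shared surfaces raised these correlations was not tested. Calls existed for 1 material, so no overlap of calls arose.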

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

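The surface comparison, the clustering of called features and the shared-surface block were tests chosen after their results had been seen. The estimated correlation was a planned setting weighed here after its result was seen, and the removal of the surface trend was added after the data had been seen; the splits of the samples and the other features of the called genes were set out before.

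Surface marks recurred 20 or 40 columns apart, and 0 of 46 samples matched a labelled array partner best. A candidate explanation is that columns and labels of the table are out of step. The alternative that only the array names are wrong while the groups are right needs replicates to resemble each other; a permutation test of that gave p = 0.472 and stays open, since small effects would give it too. Which sample belongs to which material was not worked out from the values. No biological explanation was tested for this pattern.

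The decrease of genes in samples labelled Fullerene 6 h may come from marks at single spots: 15 of the 69 genes had another feature with a mean above 9, and these other features had a median log2 fold change of -0.26, against -2.33 for the called features of the same genes. Of the 15 genes, 10 had other features below 0, the lowest at -1.005. The called features were chosen for their change in these same data, so part of the gap may come from that choice. The called features also clustered on the array (permutation test, p = 1e-04, the smallest that 10000 draws can give). Once the smooth surface component was removed, 73 of the 91 calls, higher and lower together, remained. In all 102 genes were then called, 91 of them lower. This argues against that component as the whole cause, but not against other differences between arrays. Over all genes, columns 20 or 40 apart still correlated with a mean r of 0.57 after the removal, against 0.63 before. Replicates 2 and 3 shared surface marks, and with a block of such columns 3 genes passed. These 2 replicates lay in columns 23 and 43, among the columns whose actin list means stood apart and which held no control. For them a difference of these columns cannot be told apart from an effect of the material. An effect of the material on part of the genes stays open.

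The 22 list calls could reflect members that vary together: 0 lists were called with an estimated correlation. Of 100 labellings within a time, the real one included, 89 gave at least 22 calls. The relabelled draws had a median of 37 calls and a highest of 67. The real count lay below that median, so it gives no evidence against chance.

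Of the 84 splits of the Fullerene 6 h and control samples, 2 gave at least 91 genes, the real one included, a share under 0.05, and the highest other gave 358. Whether chance is excluded stays open, because the splits treat samples as exchangeable while replicates 2 and 3 shared a surface. This contrast was also picked out of 12 material contrasts, as the only 1 with calls. In the other 11 material contrasts the real count was 0, which every split reaches, so the 84 of 84 splits with as many decide nothing. The highest other splits at 6 h gave 1552 genes for rCNT, 220 for tCNT, 1565 for Baytube, 90 for Graphite and 17 for SES. At 24 h they gave 9 for rCNT, 14 for tCNT, 14 for Baytube, 7 for Graphite, 60 for Fullerene and 8 for SES. The highest splits of rCNT and Baytube at 6 h, against a real count of 0, may point to a structure of the samples other than the labelled groups, or to calls arising together among correlated genes, which was not tested. For the 27 genes of the F-test at 6 h, 12 of 100 draws gave as many, the real grouping included, with a highest other of 503, and chance is not excluded. At 24 h the real count was 0, which every draw reaches, and the highest other was 290. The control time contrast and the 6 time differences also had a real count of 0, so the 100 of 100 draws as large decide nothing. Their highest other was 1 for time, 4 for rCNT, 1 for tCNT, 49 for Baytube, 0 for Graphite, 5 for Fullerene and 0 for SES. For rCNT against tCNT and for the 2 control sets, 10 splits are too few for a share under 0.05; the real counts were 0, and the highest others were 6 and 1 for rCNT against tCNT at 6 h and 24 h and 0 for the control sets at both times.

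One control sample stood apart from the other 5 in 11 of 108 values tested, where chance gives 5.4. The gap to the nearest sample as a share of the range was 0.691 for heat shock chaperones, 0.676 for the unfolded protein response, 0.653 for cholesterol synthesis and 0.788 for EIF4A3, all low in control 6 h replicate 5. It was 0.643 for hypoxia and glycolysis and 0.75 for CLDN5, high in control 6 h replicate 4, and 0.725 for YWHAB, low in replicate 3. At 24 h it was 0.72 for cholesterol efflux, low in replicate 1, 0.651 for macrophage markers, high in replicate 1, 0.795 for oxidative phosphorylation, high in replicate 4, and 0.77 for EIF4A3, high in replicate 6. Control 6 h replicate 5 had a surface SD of 0.52, against a median of 0.11 over all samples. Its surface correlated at 0.99 with that of Graphite 24 h replicate 1.

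The effect at 24 h minus that at 6 h differed in 16 of 198 list tests by cameraPR and in 0 with an estimated correlation. Of the 18 chemokine probes 8 reached 15.97 to 15.99, near the end of the scale at 16.00, so the size of the chemokine differences is uncertain. SOD2 and NFKBIA of the NF-kB list, IL1B and IL1RN of the cytokine list and IER3 of the immediate early list also reached 15.97 to 16.00. The sizes of those differences are uncertain too. For tCNT the mean difference was -1.70 for NF-kB genes, -1.30 for chemokines, -1.07 for proinflammatory cytokines, -0.90 for immediate early genes and 0.59 for monocyte and promyelocyte markers. For Baytube it was -1.01 for chemokines, -0.95 for NF-kB genes, -0.51 for immediate early genes, -0.56 for interferon-stimulated genes and 0.23 for ribosomal proteins, whose probes lay near the end of the scale at 16.00, so that no change is read from it. For Graphite it was -0.74 for NF-kB genes, -1.33 for metallothioneins and -0.99 for cholesterol synthesis. For rCNT it was 0.61 for metallothioneins and 0.95 for proliferation genes, and for Fullerene 0.88 for proliferation genes.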

How the results depend on the processing

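The alternatives on the surface were chosen after seeing the data. The 91 genes of Fullerene 6 h numbered 89 with no block by dye and 82 with the replicate letter as a block, which changed no other count by over 1.5 times. They numbered 59 with the mean of a gene's features, 14 and 4 with controls of code 1 and 6, 0 with the contrast's own groups, 3 with the shared-surface block and 925 without the 6 samples of the strongest surface trend. Those 6 included Fullerene 6 h replicate 1. Replicates 2 and 3, which were left, shared surface marks (r = 0.79), so the 925 calls rest on samples that are not independent. The 27 genes of the F-test at 6 h became 13 with the labelled slide as a term, 0 with its own groups and 0 with the shared-surface block. They became 252 without the 6 samples of the strongest surface trend. Without them 47 genes passed for tCNT 6 h, 12 for rCNT against tCNT at 6 h, 1 for the tCNT difference and 168 for the Fullerene difference. The mean of features gave 1 for tCNT 6 h and 4 for the Fullerene difference; own groups gave 814 for Graphite 24 h and 8 for the Fullerene difference. The 22 list calls became 38 with own groups, 61 with the shared-surface block and 0 with an estimated correlation. Of the 22 themselves, 8 were lost with the labelled slide as a term, 4 with the shared-surface block and 5 without the samples of the strongest surface trend. With controls of code 1, 8 were lost and 1 more reversed, and with controls of code 6, 7 were lost. If columns and labels are out of step, the labelled slide cannot show a slide effect. The cause of these changes was not tested.

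Leaving out one sample gave 2 to 343 genes for Fullerene 6 h, 2 to 140 for the F-test at 6 h, 0 to 1 at 24 h, 0 to 23 for tCNT 6 h, 0 to 189 for Baytube 24 h, 0 to 1 for Baytube 6 h and for SES 6 h, 0 to 105 for the Fullerene difference, 0 to 3 for the tCNT difference, 0 to 13 for rCNT against tCNT at 6 h, 0 to 1 for the control sets at 6 h and 17 to 29 list calls. Fullerene 6 h gave 57 and 58 without control 6 h replicates 2 and 3. Mean list changes reversed on leaving out one sample of the material: for Baytube 24 h they ran from -1.304 to 0.0778 for chemokines and from -1.201 to 0.0435 for NF-kB genes, positive without replicate 1. For Baytube 6 h they ran from -0.0261, without replicate 3, to 1.227 for proliferation and from -0.1748 to 0.0299, without replicate 2, for ribosomal proteins. For interferon-stimulated genes in SES 6 h the mean was -0.0581 with controls of code 1. Signal over background was not used here, so what it limits is unknown.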

Other observations

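Some genes of inflammation and cell division, and CYP1B1, varied strongly between samples. Genes of other lists did so too, such as FDPS of cholesterol synthesis, which ranged over 8.68 on the log2 scale. TNF ranged over 6.20 on the log2 scale (n = 48) and TOP2A over 4.38. CCL20, a chemokine, ranged over at least 9.28, CXCL8, the neutrophil chemokine, over at least 6.64, and CYP1B1, a dioxin-responsive monooxygenase, over at least 6.59. These 3 are lower bounds, since the highest values of 15.97 to 15.99 lay at the end of the scale, and the lowest of CCL20, 6.71, near its bottom. The labelled group held 21.2% of the variance of CCL20, 9.22% for CXCL8, 18.4% for CYP1B1, 18.4% for TNF and 16.5% for TOP2A. These shares lay below the 27.6 to 27.7% expected by chance for list means with the same groups. More was held for other members of the lists: 52.4% for HSPA1B, 49.98% for CSF3, whose mean of 7.18 lay near the bottom of the scale, 40.5% for TNFAIP2, 37.2% for CCL24 and 34.1% for MCM7. These genes were chosen after their values were seen, and no gene was tested. Members of the proliferation list correlated with a mean r of 0.707 and those of the NF-kB list with 0.553.

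Sets of columns 20 or 40 apart held 96.3% of the variance of the actin cytoskeleton list, against 40.4% expected by chance (permutation test, p = 1e-05, the smallest possible), and 85.4% for the unfolded protein response. They held 30.3% for proliferation genes (permutation test, p = 0.8) and 49.1% for NF-kB genes (permutation test, p = 0.2). These values were examined after the surface marks had been seen, and no cause was tested.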
